A study of Mus musculus with 10 samples.

How the data were processed

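Per the labels' protocols, mice were treated from 30 days after tumor induction, at a volume under 100 mm3, for up to 30 days or until 2 cm3. Tumors were digested, red cells were lysed with ACK buffer, and dead cells were removed on a density gradient; the protocol text names no step that selects T cells. The inhibitor was given in chow at 600 mg/kg and the antibody by intraperitoneal injection at 10 mg/kg every 3 days, up to 10 doses. Libraries were made from 50 ng of RNA with a SMARTer ultra low input kit, without strand information, and sequenced as 75-base paired reads on an Illumina HiSeq with 6 libraries per lane. Per the submitters' processing notes, reads were aligned to GRCm38 (mm10) with STAR, counted with HTSeq and normalized with DESeq2. The versions are not given, nor is the release of the gene annotation.

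The deposited values are scores, which the authors made before deposit by dividing the counts per gene by size factors and rounding to whole numbers. Median-of-ratios factors computed again from these values lay within 0.2% of each other, so they were used as normalized counts without further scaling. Of the 48825 genes, 25779 were at 0 in every library and 11713 above 0 in every library. Among the names, 27 had been turned into numbers and 2 occurred repeatedly. No pair of libraries shared more than 0.554% of its compared values. Whole reads could not be recovered from the rounded values in all libraries, so tools that need whole reads were not run.

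Genes with at least 10 normalized counts in at least 2 libraries were kept, which left 15716. Values were taken to log2 after adding 1. A linear model with the 4 groups was fitted in limma 3.58.1 (R 4.3.3), with a trend of the variance on the mean and 6 residual and 5.48 prior degrees of freedom. The 8 contrasts were each treatment and the combination over control, the combination over each treatment, the interaction, and the effect of each treatment averaged over both levels of the other. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes of 1 contrast. Numbers in the titles were not used to pair the libraries in the main fit. For same-number pairs across groups, correlations of the departures from the group means ran from -0.27 to 0.18. With 2 or 3 libraries per group these neither show nor exclude a pairing. An alternative, the replicate block, took the number as a block in the groups other than CSF1Ri. The groups have 2 or 3 libraries, so where a fit leaves 1 library in a group, that library is assumed to vary like those of the other groups. Leaving out a library of a group that is not compared changes the shared spread and the genes tested, but not the log2 fold change of a gene.

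The groups, contrasts, threshold, filter, alternatives, 38 gene lists and the rule for naming genes were chosen before the data were examined. The lists hold 807 entries, of which 805 were matched to the table. Lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated per list, and with fry, which tests a list by itself. Adjusted p of lists cover the 38 lists of a contrast, and a count over the list alone adjusts over the members of that list. Named genes were those past the threshold with a mean of at least 50 and groups that did not overlap, up to 10 per direction against control and 5 otherwise. Where none passed, the 3 with the smallest p were named as not past it. The rule adds 2 to 4 members with the smallest p of each list described, and genes always given, of which 18 are reported. Many lists are given by their counts and test alone, so not every gene that the rule names is reported here. Genes that passed only when a library was left out, and values given for other genes, were chosen after their values were seen.

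A fold against a group at 0 was counted against a floor of 3 counts per library. Counts of closely related genes, such as the globin genes, the mast cell tryptases and the interferon-induced GTPases, depend on how reads shared between them were assigned. Positions of genes are from the GENCODE vM21 annotation of GRCm38. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the other steps.

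In 5 simulated sets per comparison, the spread of each gene was estimated from these libraries and drawn toward its trend on the mean. Changed genes were picked among those with a mean of at least 100, so the shares do not cover lower genes. Genes changed by 2-fold were recovered at 17.6% for CD40, 12% for CSF1Ri and 10.8% for the combination over control. At 4-fold the shares were 71.6%, 61.2% and 64.8%, and at 16-fold 97.2%, 96.8% and 98%. Each share is out of 250 changed genes over the 5 sets. With many changed genes per set, the adjusted threshold is easier to pass than in the real comparisons, where 0 or 1 gene passed. The shares therefore overstate how often a lone changed gene would pass. False calls numbered 27, 26 and 22 of 77580 tests. For the combination over control, a shifted list was found in 5 of 5 sets, and 0 of 175 unchanged lists were called. Genes were drawn independently of each other in these sets, so this says nothing of how often lists of correlated genes are called by chance at the preset correlation. The false calls likewise leave out any structure that the real libraries share. A split of the real control and CD40 libraries that does not follow treatment gave 112 genes. Of 100 splits of the real libraries per averaged effect, the real one included, 57 gave at least 10 lists for the inhibitor and 31 at least 13 for the antibody.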

Results

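Transcripts of tumor-infiltrating T cells were measured by bulk RNA sequencing in a mouse model of melanoma, in which an inducible recombinase in melanocytes activates an oncogenic Braf allele. The 10 libraries fell into 4 groups. Control mice gave 3 libraries, mice fed chow with the CSF1R inhibitor PLX6134 (CSF1Ri) gave 2, mice given the agonistic CD40 antibody FGK4.5 (CD40) gave 3, and mice given both (CSF1Ri+CD40) gave 2. Libraries carry the number in their title, except that the title of 1 CSF1Ri library has none, and it is called CSF1Ri 1 here. CSF1R is the receptor through which macrophages receive their main survival signal. CD40 is a receptor of dendritic cells, macrophages and B cells that licenses them to activate T cells. The series concerns treatments aimed at myeloid cells, alone and together, so the comparisons ask how transcripts of T cells, which are not the direct target, differed under each treatment. Every library was a pool of at least 3 tumors, and the p-values measure the spread between these pools.

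The deposited normalized counts summed to 11941067, 12689076 and 12076535 in the control libraries 1, 2 and 3, and to 12513603 and 12736201 in the CSF1Ri libraries 1 and 6. They summed to 12840634, 14024851 and 11538244 in the CD40 libraries 1, 2 and 3, and to 12693982 and 12750973 in the CSF1Ri+CD40 libraries 1 and 3. These totals are scaled and are not read depths. Reads in genes, estimated from the spacing of the values, ran from 10.3 M in CSF1Ri+CD40 3 to 15 M in CSF1Ri 1 (M, mega, reads), and could not be estimated for control 1 and CD40 3. Of the 48825 genes listed, 15716 held at least 10 normalized counts in at least 2 libraries and were tested. Ranks of the 8844 genes with a mean of at least 100 correlated across genes at rho 0.795 to 0.941 within groups and at 0.821 to 0.931 between groups.

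The titles name T cells, whereas the tissue field of the labels names macrophages of the tumor. Transcripts of the T cell receptor complex were abundant and those of the macrophage receptor were low. In the order control, CSF1Ri, CD40 and CSF1Ri+CD40 (mean ± SD, n = 3, 2, 3 and 2), Cd3e averaged 15740 ± 6343, 21170 ± 2442, 17490 ± 518 and 22750 ± 487 normalized counts. Csf1r averaged 112 ± 7.21, 116 ± 24.0, 148 ± 75.8 and 35.5 ± 7.78. Cd40 averaged 184 ± 157, 174 ± 36.8, 217 ± 182 and 121 ± 50.2. Cd40lg, its ligand on activated helper T cells, averaged 775 ± 219, 978 ± 80.6, 791 ± 61.7 and 590 ± 82.7.

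Lineage, state and effector genes are given in the same order and unit. Cd4 averaged 2245 ± 110, 4048 ± 646, 3099 ± 554 and 3303 ± 1273, and Cd8a 1692 ± 218, 3454 ± 327, 2581 ± 1456 and 4366 ± 822. Foxp3, the master regulator of regulatory T cells, averaged 2267 ± 563, 1739 ± 144, 2006 ± 613 and 2452 ± 313. Among inhibitory receptors, Pdcd1 (PD-1) averaged 1956 ± 296, 5192 ± 6.36, 3413 ± 1902 and 4500 ± 1663. Ctla4 averaged 8216 ± 670, 6842 ± 948, 6725 ± 2285 and 7810 ± 190. Lag3 averaged 124 ± 37.2, 256 ± 30.4, 350 ± 78.9 and 475 ± 141, and Havcr2 (TIM-3) 410 ± 177, 797 ± 220, 449 ± 182 and 766 ± 122. Of the killing machinery, Gzmb averaged 2558 ± 762, 3896 ± 1182, 4587 ± 2438 and 5936 ± 1364, and Prf1 (perforin) 206 ± 73.9, 572 ± 291, 452 ± 106 and 857 ± 24.7. The cytokine gene Ifng averaged 834 ± 253, 1214 ± 81.3, 1604 ± 1264 and 2206 ± 86.3. Tnf averaged 377 ± 74.4, 419 ± 47.4, 598 ± 193 and 255 ± 127, and Il2 266 ± 114, 269 ± 112, 255 ± 177 and 190 ± 26.9. Tcf7, a transcription factor of naive and memory-like cells, averaged 3696 ± 1538, 3021 ± 14.1, 2611 ± 1554 and 2032 ± 506. Mki67, a marker of cycling cells, averaged 1834 ± 496, 1424 ± 434, 1910 ± 326 and 2118 ± 47.4. None of these 18 genes passed an adjusted p under 0.05 over all genes in any of the 8 comparisons (limma).

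Some libraries stood apart in ways the groups do not explain. CD40 2 and CD40 3 lay far from the others and from each other on the first 2 principal components, at 40.8 and 61.8 and at -64 and 32.4. The nuclear noncoding RNA Malat1 ran from 14056 normalized counts in control 2 to 95260 in CD40 3. The Y-linked transcripts Ddx3y, Eif2s3y, Kdm5d and Uty summed to 2438 normalized counts in control 1, to 1569 in CD40 2 and to 3072 in CD40 3. They summed to 0 or 1 in the other libraries, so no library with the inhibitor held them above 1. In every fit on only the 7 libraries without them, CD40 1 is the only CD40 library. Hemoglobin transcripts summed to 12899, 15721 and 2855 in the control libraries, 1288 and 2695 with CSF1Ri, 811, 1171 and 838 with CD40, and 13 and 474 with both.

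With the CSF1R inhibitor alone, gene lists of T cell identity, activation, cytotoxic and type 1 helper function rose and keratinocyte genes fell at a preset correlation, and no list passed with an estimated correlation (smallest adjusted p = 0.27). Il2rb, a receptor chain for interleukins 2 and 15, averaged 6524 ± 58.0 normalized counts (SD, n = 2) against 3541 ± 939 in control (SD, n = 3). Cd38, an ectoenzyme of activated T cells, averaged 521 ± 19.8 against 191 ± 52.1. The gene past the threshold over all genes was Anxa8 (chromosome 14, 34085981 to 34100571), an annexin of epithelial cells. It was at 0 in both CSF1Ri libraries and at 145 ± 54.6 in control, at least 48.2-fold lower against a floor of 3 counts per library (adjusted p = 0.0383, limma).

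Of the 20 T cell identity genes, 19 were higher than in control, with a median log2 fold change of 0.35. Cd4 had a log2 fold change of 0.84, Cd6 of 0.67, Cd247, the signaling chain of the T cell receptor, of 0.46, and Cd8a of 1.03, and 0 members passed adjusted over the list alone. The list rose with an adjusted p = 1.11e-06 in camera at a preset correlation, and with an adjusted p = 0.27 with an estimated correlation. Of the 24 genes of activation and costimulation, 19 were higher. Over the list alone 3 rose, 1 fell and 20 did not pass. Il2rb, Cd38 and Cd7 rose, the last from 3110 ± 853 to 5465 ± 281 normalized counts, and Nr4a1, an immediate target of T cell receptor signaling, fell from 1011 ± 403 to 368 ± 109. This list had an adjusted p = 0.00108, and an adjusted p = 0.27 with an estimated correlation.

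Of the 21 cytotoxic effector genes measured, 18 were higher and 0 passed over the list alone. The list rose (adjusted p = 0.000953, and adjusted p = 0.64 with an estimated correlation). Prf1 had a log2 fold change of 1.43 and Ctsw, a protease of killer cells, of 1.11. Klrg1, a receptor of terminally differentiated effector cells, stood at 1780 ± 169 normalized counts against 3062 ± 533 (adjusted p over the list alone 0.0609). The type 1 helper list rose, with 12 of 14 members higher and 0 past the threshold over the list alone (adjusted p = 0.00159, and adjusted p = 0.5 with an estimated correlation). Il12rb2, a chain of the interleukin 12 receptor, had a log2 fold change of 3.19, Stat4, its signal transducer, of 1.02, and Cxcr3, a receptor for interferon-induced chemokines, of 1.07. Inhibitory receptors and exhaustion genes rose as a list, with 14 of 20 higher and 0 past the threshold over the list alone (adjusted p = 0.0271, and adjusted p = 0.35 with an estimated correlation). Its mean level relative to control was 0.431 in CSF1Ri 1 and -0.128 in CSF1Ri 6, so that without CSF1Ri 1 the direction turned, and the call ended without CSF1Ri 1 or control 2 (adjusted p up to 0.32). Pdcd1 had a log2 fold change of 1.42 and Entpd1, the ectonucleotidase CD39, of 0.86.

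Keratinocyte markers were lower for 10 of 11 measured members, with a median log2 fold change of -2.57, or -2.35 with genes at 0 counted at the floor. The list fell (adjusted p = 1.11e-06, and adjusted p = 0.27 with an estimated correlation). Krt5, a keratin of basal cells, averaged 33.0 ± 42.4 against 142 ± 53.7 and Sfn 87.5 ± 19.1 against 341 ± 155, neither past the threshold over the list alone. The 5 measured erythroid genes were all lower, with a median of -2.09 (adjusted p = 0.000627, and adjusted p = 0.56 with an estimated correlation). The 7 measured mitochondrially encoded transcripts were all lower, with a median of -0.37 (adjusted p = 0.0034, and adjusted p = 0.67 with an estimated correlation). Cytosolic ribosomal protein genes were higher for 70 of 76, with a median of 0.18 (adjusted p = 1.2e-06, and adjusted p = 0.67 with an estimated correlation). The interferon gamma response rose, with 20 of 28 higher (adjusted p = 0.0242, and adjusted p = 0.52 with an estimated correlation). Glycolysis (16 of 21 higher, adjusted p = 0.0379) and MHC class I presentation (14 of 22 higher, adjusted p = 0.049) also rose. Fibroblast markers (11 of 13 lower, adjusted p = 0.0483) fell, and the NF-kB response had 18 of 27 lower (adjusted p = 0.049). The NF-kB list stood at 0.395 in CSF1Ri 1 and at -0.991 in CSF1Ri 6, and without CSF1Ri 6 its direction turned (adjusted p up to 0.98). The glycolysis, MHC class I, fibroblast and NF-kB lists each had an adjusted p = 0.67 with an estimated correlation. None of the lists in this paragraph had a member past the threshold over the list alone.

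In all, 14 of the 38 lists passed at the preset correlation and 0 at the estimated one, and 1 gene passed while 641 had an unadjusted p under 0.05, against 786 expected by chance. Leaving out 1 library moved this number at an unadjusted p under 0.05 from 204 without CSF1Ri 6 to 882 without CD40 3. The call of Anxa8 ended in each of the 10 fits that left out 1 library, with adjusted p from 0.0687 without CD40 3 to 0.472 without control 3. Without a CD40 or CSF1Ri+CD40 library its fitted log2 fold change stayed at -7.10, as those libraries are not compared here. The calls of T cell identity, activation, cytotoxic, keratinocyte and ribosomal genes held in all 10 such fits. The type 1 helper call ended without CSF1Ri 6 (adjusted p = 0.065) and the erythroid call without CSF1Ri 1 (adjusted p = 0.051), while the other 7 list calls each ended in 2 to 7 of these fits. With a term for Y-linked transcripts, chosen after seeing the data, the interferon gamma, MHC class I, glycolysis and NF-kB calls ended (adjusted p of 0.069, 0.069, 0.094 and 0.13). With only the 7 libraries without these transcripts the interferon gamma, MHC class I and NF-kB calls ended (0.078, 0.052 and 0.42), and with a term for Malat1 those of MHC class I, glycolysis and NF-kB (0.12, 0.076 and 0.068).

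With the CD40 antibody alone, the type 17 cytokine genes were lower. Il17a (chromosome 1, 20730905 to 20734496), which encodes a neutrophil-recruiting cytokine of type 17 and gamma delta T cells, averaged 256 ± 199 normalized counts (SD, n = 3) against 3692 ± 520 in control (SD, n = 3). This was a log2 fold change of -4.10 ± 0.413 (SE), or 17.2-fold (adjusted p = 0.00879, limma). Every CD40 library, at 485, 155 and 128, lay below the lowest control library, at 3182. Its neighbor Il17f (chromosome 1, 20777146 to 20790617) averaged 777 ± 1110 against 5498 ± 2040. Il22 (chromosome 10, 118204942 to 118210047), a cytokine that acts on epithelium, averaged 27.0 ± 35.0 against 239 ± 51.9.

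Of the 17 measured genes of the type 17 and gamma delta program, 16 were lower with CD40 (median log2 fold change -1.21). Over the list alone 9 fell, against 1 over all genes. Beside the cytokines these included Il1r1, the interleukin 1 receptor, at 326 ± 280 against 1000 ± 321 normalized counts. Il23r, a chain of the interleukin 23 receptor that sustains these cells, was at 33.3 ± 32.7 against 124 ± 26.2, and Blk, a kinase of gamma delta T cells, at 920 ± 532 against 2324 ± 758. The transcription factor gene Maf was at 4909 ± 1920 against 9138 ± 3750, and Trdc, the constant region of the delta receptor chain, at 3972 ± 1790 against 6639 ± 1170. The list fell with an adjusted p = 1.59e-11 in camera, and with an adjusted p = 0.42 with an estimated correlation. In fry its adjusted p was 0.42 for a change of the members 1 way on balance and 0.033 for a change in either direction.

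Mast cell and basophil markers were higher for all 10 members (median 2.77), and 5 rose over the list alone. The list had an adjusted p = 5.49e-07, and an adjusted p = 0.42 with an estimated correlation. Cpa3, a mast cell protease, averaged 1749 ± 2100 against 150 ± 164, with 4168 counts in CD40 1 and 422 and 657 in CD40 2 and 3. Fcer1a, the IgE-binding receptor chain, averaged 327 ± 123 against 60.7 ± 45.7. Mitochondrially encoded transcripts were lower for all 7 measured members, of which 6 fell over the list alone (median -0.80, adjusted p = 1.28e-07, and adjusted p = 0.42 with an estimated correlation). Of these, mt-Nd4 averaged 9867 ± 2300 against 18880 ± 4800. CD40 3, the library highest in Malat1, had the lowest sum of mitochondrial transcripts, at 123380. The groups overlapped: control 1 summed to 228238, below CD40 1 at 261965 and CD40 2 at 241918. Control 2 and control 3, at 339720 and 370442, lay above all CD40 libraries. Erythroid genes were lower for 5 of 5, of which 3 fell over the list alone (median -3.03, adjusted p = 2.41e-05, and adjusted p = 0.42 with an estimated correlation). Hba-a1, an alpha globin gene, averaged 355 ± 106 against 3611 ± 2390. Keratinocyte markers were lower for 8 of 11 (adjusted p = 0.00411, and adjusted p = 0.47 with an estimated correlation). Krt1, a keratin of the upper skin layers, fell over the list alone, from 87.3 ± 84.4 to 0.333 ± 0.577. Fibroblast markers were lower for 11 of 13 (adjusted p = 0.0413, and adjusted p = 0.71 with an estimated correlation), but their mean log2 fold change turned from -1.49 to 0.42 without CD40 3.

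T cell identity rose, with 18 of 20 higher (median 0.27, adjusted p = 0.000452), as did MHC class I presentation, with 19 of 22 higher (median 0.29, adjusted p = 0.00035). Each had an adjusted p = 0.42 with an estimated correlation and 0 members past the threshold over the list alone. H2-T23, a nonclassical class I molecule, averaged 10560 ± 3230 against 6392 ± 1530. Ribosomal protein genes (69 of 76 higher, adjusted p = 4.47e-08), glycolysis (17 of 21, adjusted p = 0.00229) and MHC class II presentation (11 of 14, adjusted p = 0.045) rose, and immediate early genes fell (18 of 27 lower, adjusted p = 0.0413). Each of these 4 lists had an adjusted p = 0.68 with an estimated correlation. Oxidative phosphorylation rose, with 30 of 38 higher (adjusted p = 0.0134, and adjusted p = 0.75 with an estimated correlation). Its mean log2 fold change turned to -0.00232 without CD40 2, and that of MHC class II to -0.00151 without CD40 1. Members of lists that did not pass also passed over their own list. Cxcr4, the receptor for the chemokine CXCL12, fell from 1844 ± 248 to 804 ± 115, and Tnfaip3, a brake on NF-kB signaling, from 5383 ± 1230 to 1518 ± 617. Lag3 rose by 1.51 on the log2 scale and Cd7 by 0.98.

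The call of Il17a ended without control 1, control 2, control 3 or CD40 2 (adjusted p of 0.0874, 0.111, 0.146 and 0.0969). It also ended with only the 7 libraries without Y-linked transcripts, an alternative chosen after seeing the data. CD40 1 is then the only CD40 library, and the log2 fold change was -3.02. The call ended too with the replicate block, without the trend, without the filter and with only the libraries compared (adjusted p of 0.133, 0.132, 0.0548 and 0.923). Over its 25 alternatives the log2 fold change ran from -4.69 to -3.02 and the adjusted p from 4.72e-05 to 0.923. In all, 1 gene and 13 of 38 lists passed, with 0 lists at the estimated correlation, and 1005 genes had an unadjusted p under 0.05, against 786 expected by chance. Leaving out 1 library moved this number at an unadjusted p under 0.05 from 676 without control 1 to 2039 without CD40 3, so it does not stay above chance. Without CD40 1 the count was 3: Il17a, Il17f and Osgin1. The fibroblast and keratinocyte calls ended without control 3 or CD40 3 (adjusted p up to 0.39 and 0.16), the glycolysis call without CD40 2 (0.23), and those of oxidative phosphorylation, MHC class II and immediate early genes in 4 to 8 fits each. The fibroblast call also ended with a Y-linked term (adjusted p = 0.39), and the fibroblast and immediate early calls with a Malat1 term (adjusted p of 0.12 and 0.075). With only the libraries without Y-linked transcripts, where CD40 1 is the only CD40 library, the keratinocyte and immediate early calls ended. The means of the fibroblast and keratinocyte lists turned positive there, so neither fall held. CD40 1 itself stood at 1.55 for fibroblast and 0.0602 for keratinocyte markers relative to the control mean.

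With both treatments, lists of T cell killing, of inhibitory receptors and of the response to interferon gamma were higher than in control at a preset correlation, though not with an estimated correlation (smallest adjusted p = 0.061). Hemoglobin transcripts, at 13 and 474 counts in the libraries 1 and 3, were lower than in control, where they ran from 2855 to 15721. Gzmk (chromosome 13, 113171608 to 113225908), a granzyme of effector memory CD8 T cells, averaged 2571 ± 113 normalized counts (SD, n = 2) against 185 ± 143 in control (SD, n = 3). Entpd1 (chromosome 19, 40612366 to 40741602) averaged 1394 ± 407 against 311 ± 58.8. Lilrb4a (chromosome 10, 51490956 to 51496611), an inhibitory receptor of myeloid and activated lymphoid cells, averaged 954 ± 19.8 against 244 ± 35.6. Hbb-bt (chromosome 7, 103812524 to 103813996), a beta globin gene, averaged 5.00 ± 7.07 against 927 ± 554. No gene passed an adjusted p under 0.05 over all genes (limma, 849 at an unadjusted p under 0.05). The 3 smallest adjusted p were 0.0708 for Hbb-bt and 0.216 for Entpd1 and for Lilrb4a.

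Of the 21 measured cytotoxic effector genes, 19 were higher (median 0.72) and 3 rose over the list alone. These were Gzmk, with a log2 fold change of 4.14 ± 0.687 (SE), Prf1, at 857 ± 24.7 against 206 ± 73.9 normalized counts, and Slamf7, a receptor of cytotoxic cells, at 998 ± 133 against 356 ± 150. Gzmb had a log2 fold change of 1.24 (adjusted p over the list alone 0.0588). The list rose with an adjusted p = 4.32e-08, and with an adjusted p = 0.22 with an estimated correlation. Of the 20 inhibitory receptor and exhaustion genes, 19 were higher (median 0.66) and 3 rose over the list alone: Entpd1, Lag3 (475 ± 141 against 124 ± 37.2) and Tigit (5568 ± 126 against 2841 ± 1120). This list had an adjusted p = 1.14e-06, and an adjusted p = 0.061 with an estimated correlation. In fry, which asked here whether members move 1 way on balance, its adjusted p was 0.042. Of the 28 measured interferon gamma response genes, 25 were higher (median 0.61, adjusted p = 7.51e-09). This list had an adjusted p = 0.061 with an estimated correlation and 0.042 in fry. Iigp1, an interferon-induced GTPase, rose over the list alone (2631 ± 97.6 against 981 ± 205). Irf1, a transcription factor of the response, had a log2 fold change of 0.75 and Igtp of 0.71, not past the threshold.

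**Figure D1:**
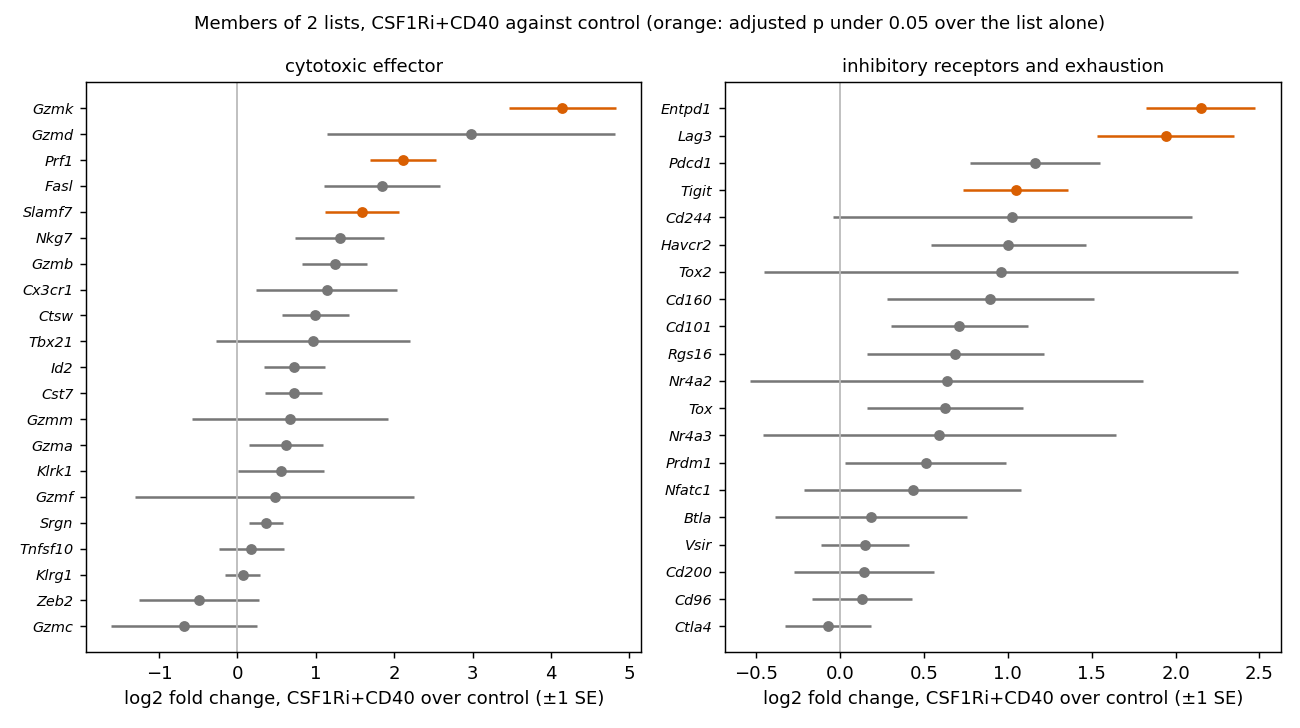
Log2 fold change of each measured member of the cytotoxic effector list (left) and the list of inhibitory receptors and exhaustion (right), CSF1Ri+CD40 (n = 2) over control (n = 3), with bars of ±1 SE. Members with an adjusted p under 0.05 over the list alone are orange (3 in each list), and 19 of 21 cytotoxic and 19 of 20 inhibitory and exhaustion genes lie above 0.

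Activation and costimulation genes rose as a list, with 17 of 24 higher (adjusted p = 0.00647, and adjusted p = 0.22 with an estimated correlation). Cd38 (chromosome 5, 43868553 to 43912375) rose over the list alone, at 1016 ± 540 against 191 ± 52.1. Type 1 helper genes rose, with 11 of 14 higher (adjusted p = 0.00145, and adjusted p = 0.25 with an estimated correlation). Bhlhe40, a regulator of cytokine production, had a log2 fold change of 0.87 and Cxcr3 of 1.29, neither past the threshold over the list alone. Cytokine and chemokine genes rose, with 16 of 24 higher (adjusted p = 0.0331, and adjusted p = 0.66 with an estimated correlation). Ccl3, a chemokine of activated CD8 T cells, rose over the list alone (1452 ± 535 against 198 ± 69.9), and Il17a fell by 1.75 on the log2 scale. T cell identity (18 of 20 higher, median 0.33, adjusted p = 5.15e-05) and MHC class I presentation (21 of 22 higher, median 0.33, adjusted p = 9.69e-06) rose. Each had an adjusted p = 0.22 with an estimated correlation. Cd8a and Cd8b1, the chains of the CD8 co-receptor, had log2 fold changes of 1.36 and 1.14, not past the threshold. Glycolysis rose, with 18 of 21 higher (adjusted p = 7.01e-05, and adjusted p = 0.42 with an estimated correlation). Hypoxia genes rose, with 16 of 21 higher (adjusted p = 0.0296, and adjusted p = 0.22 with an estimated correlation). Slc2a1, the glucose transporter GLUT1 and a member of both, rose over each list alone (1138 ± 312 against 501 ± 47.6). Ribosomal protein genes rose, with 62 of 76 higher (adjusted p = 0.00107, and adjusted p = 0.83 with an estimated correlation).

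All 5 measured erythroid genes fell over the list alone, with a median of -5.95 (adjusted p = 3.55e-14, and adjusted p = 0.1 with an estimated correlation). Hba-a1 averaged 101 ± 128 against 3611 ± 2390, and in fry the list had an adjusted p of 0.042. The mean log2 fold change of the list ran from -8.67 without CSF1Ri+CD40 3 to -4.12 without CSF1Ri+CD40 1. Mast cell markers rose as a list, with 9 of 10 higher and a median of 2.48 (adjusted p = 5.23e-06, and adjusted p = 0.25 with an estimated correlation). Tpsb2, a mast cell tryptase, was at 3007 counts in CSF1Ri+CD40 1 and at 482 in CSF1Ri+CD40 3, and without CSF1Ri+CD40 1 the mean of the list was 1.07, against 2.03 with all. B cell and plasma cell markers fell, with 12 of 15 lower (adjusted p = 0.0089, and adjusted p = 0.25 with an estimated correlation). Jchain, the joining chain of secreted immunoglobulin, was at 0 in both libraries and between 24 and 611 in control. Macrophage markers fell, with 13 of 19 lower and a median of -1.21, or -0.96 with genes at 0 counted at the floor (adjusted p = 0.0494, and adjusted p = 0.77 with an estimated correlation). Csf1r had a log2 fold change of -1.65, Cd68 of 1.32, and C1qc, a complement chain of macrophages, was at least 13-fold lower. The type 17 program fell, with 13 of 17 lower and 1 past the threshold over the list alone (median -0.86, adjusted p = 7.73e-05, and adjusted p = 0.43 with an estimated correlation). Mitochondrially encoded transcripts fell, with 7 of 7 lower (median -0.50, adjusted p = 0.000565, and adjusted p = 0.47 with an estimated correlation).

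**Figure D2:**
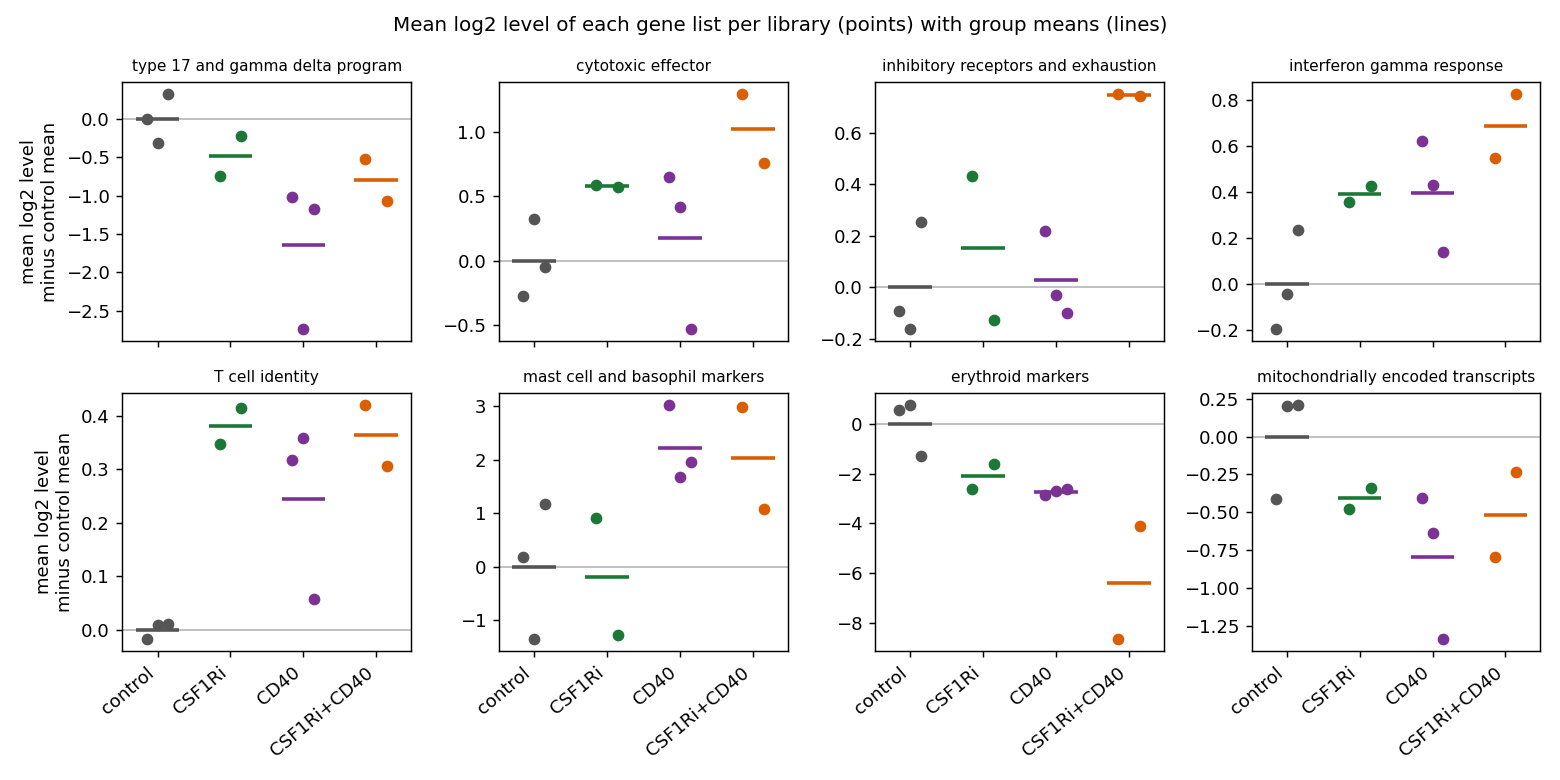
Mean log2 normalized count of the measured genes of 8 lists in each library (points), minus the mean of the control libraries, with the mean of each group (lines), for control (n = 3), CSF1Ri (n = 2), CD40 (n = 3) and CSF1Ri+CD40 (n = 2). The inhibitory receptor list lies at 0.743 and 0.751 in the CSF1Ri+CD40 libraries and between -0.163 and 0.431 in the others, and the type 17 list reaches its lowest level, -2.74, in a CD40 library.

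The count over all genes, 0, was 36 (35 lower) without CSF1Ri+CD40 1, 7 without CSF1Ri+CD40 3 and 1 without CD40 3. Of the 17 lists that passed, 0 did so with an estimated correlation and 3 did in fry. The calls of the cytotoxic, inhibitory receptor, interferon gamma, MHC class I, identity, type 1 helper, type 17, mast cell and erythroid lists held in every fit that left out 1 library. Those of activation (adjusted p = 0.067), glycolysis (0.44) and mitochondrially encoded transcripts (0.38) ended without CSF1Ri+CD40 1, and the other 5 ended in 2 to 8 fits each. With a Y-linked term the cytokine and hypoxia calls ended (adjusted p of 0.13 and 0.056), and with only the libraries without Y-linked transcripts the hypoxia and ribosomal calls (0.072 and 0.079).

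Against CSF1Ri alone, the combination shows what the antibody adds. Erythroid genes were lower for 5 of 5, of which 4 fell over the list alone (median -3.76, adjusted p = 3.06e-09, and adjusted p = 0.26 with an estimated correlation). The interferon gamma response was higher, with 23 of 28 members up (median 0.31, adjusted p = 0.000378, and adjusted p = 0.26 with an estimated correlation). Mast cell markers were higher for 10 of 10 (adjusted p = 9.53e-06, and adjusted p = 0.56 with an estimated correlation). Ms4a2, a chain of the IgE receptor, rose over the list alone from 1.00 ± 1.41 normalized counts (SD, n = 2) to 153 ± 81.3 (SD, n = 2). Cell cycle genes rose, with 33 of 42 higher (adjusted p = 0.00559, and adjusted p = 0.56 with an estimated correlation). Cenpe, a kinesin of the kinetochore, had a log2 fold change of 1.32, Ube2c, a ubiquitin-conjugating enzyme of mitosis, of 0.78, and Spc25 of -1.50, none past the threshold. Inhibitory receptors rose, with 11 of 20 higher (adjusted p = 0.0105, and adjusted p = 0.26 with an estimated correlation). The cytotoxic (16 of 21 higher, adjusted p = 0.0178), keratinocyte (10 of 11, adjusted p = 0.00965), NF-kB (21 of 27, adjusted p = 0.0224) and MHC class I lists (17 of 22, adjusted p = 0.0334) rose. The type 17 list fell (14 of 17 lower, adjusted p = 0.0365). With an estimated correlation these 5 had an adjusted p of 0.8, 0.64, 0.72, 0.72 and 0.89. Gzmk had a log2 fold change of 2.71, Entpd1 of 1.29, Klrg1 of 0.84 and Il22 of 4.04, none past the threshold over its list alone.

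No gene passed over all genes in this comparison (limma, 563 at an unadjusted p under 0.05). The smallest p-values were those of Anxa8 (at least 21.3-fold higher, adjusted p = 0.497), the chemokine gene Ccl6 (493 ± 58.0 against 97.0 ± 33.9 normalized counts, adjusted p = 0.876) and Hbb-bt (log2 fold change -5.84, adjusted p = 0.876). The count was 6, all lower, without CSF1Ri+CD40 1 and 1, Hbb-bs, without CSF1Ri+CD40 3. Of the 10 list calls, those of erythroid and interferon gamma genes held in every fit that left out 1 library, and the mast cell call ended without CSF1Ri+CD40 1 (adjusted p = 0.12). The other 7 ended in 2 to 4 fits each, with adjusted p up to 0.69. The mean of the erythroid list was -2 without CSF1Ri+CD40 1 and -6.55 without CSF1Ri+CD40 3, and that of the interferon gamma list 0.158 without CSF1Ri+CD40 3, against 0.296 with all.

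Against CD40 alone, the combination shows what the inhibitor adds. Type 17 cytokines were higher. Il17a averaged 1096 ± 168 normalized counts against 256 ± 199, Il17f 4184 ± 264 against 777 ± 1110 and Il22 437 ± 25.5 against 27.0 ± 35.0, and these 3 rose over the list alone. The list rose, with 13 of 17 members higher (adjusted p = 0.0186, and adjusted p = 0.81 with an estimated correlation). Cytotoxic effector genes rose, with 19 of 21 higher (median 0.49, adjusted p = 0.000195, and adjusted p = 0.71 with an estimated correlation). Gzmk (log2 fold change 2.99), Klrg1 (0.76) and Gzma (1.59) rose over the list alone. Inhibitory receptors and exhaustion genes rose, with 19 of 20 higher (median 0.51, adjusted p = 8.34e-05, and adjusted p = 0.15 with an estimated correlation). Entpd1 rose over the list alone (1394 ± 407 against 432 ± 94.2), and Prdm1, which encodes the transcription factor Blimp-1, had a log2 fold change of 1.51, not past the threshold. Interferon gamma response genes rose, with 24 of 28 higher (median 0.40, adjusted p = 0.000181, and adjusted p = 0.32 with an estimated correlation). Erythroid genes fell, all 5 over the list alone (adjusted p = 4.67e-07, and adjusted p = 0.43 with an estimated correlation). Immediate early genes rose, with 21 of 27 higher (adjusted p = 0.0449, and adjusted p = 0.81 with an estimated correlation).

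Over all genes 0 passed against CD40 alone (limma, 780 at an unadjusted p under 0.05). The smallest p-values were those of Osgin1, a gene of the oxidative stress response (338 ± 20.5 against 7.33 ± 12.7), Peo1, the mitochondrial helicase (1.50 ± 2.12 against 116 ± 77.5), and Bhlhe40 (5581 ± 574 against 2227 ± 573), each with an adjusted p = 0.537. The count was 20, all lower, without CSF1Ri+CD40 1, 3 without CD40 1 (Il17a, Il17f and Osgin1) and 1, Hbb-bs, without CSF1Ri+CD40 3. The cytotoxic call ended without CD40 3 or CSF1Ri+CD40 1 (adjusted p up to 0.31) and the type 17 call without CD40 2 or CSF1Ri+CD40 1 (up to 0.75). The immediate early call ended in 6 of 10 fits and with a Malat1 term (adjusted p = 0.1), and without CD40 3 its mean turned to -0.0826. The mean of the erythroid list was -1.38 without CSF1Ri+CD40 1 and -5.93 without CSF1Ri+CD40 3. That of the interferon gamma list ran from 0.152 to 0.428 over the fits without 1 library. Y-linked transcripts were present in 2 of the 3 CD40 libraries and in neither combination library above 1 count. With a Y-linked term the cytotoxic, type 17 and interferon gamma calls ended (adjusted p of 0.12, 0.12 and 0.057). With only the libraries without these transcripts, where CD40 1 is the only CD40 library, the cytotoxic, type 17 and inhibitory receptor calls ended.

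The interaction asks whether the combination differs from the sum of the treatments on the log2 scale, which is how synergy, the subject of the series, was tested. The type 17 cytokines departed from additivity over the list alone, with an interaction of 4.08 ± 0.653 (SE) for Il17a, 8.13 ± 1.59 for Il22 and 4.75 ± 1.36 for Il17f. Their means were lower than control with either treatment, and with both they were 1096 ± 168 for Il17a and 437 ± 25.5 for Il22, against 3692 ± 520 and 239 ± 51.9 in control. The positive sign thus means a smaller fall than the sum of the treatments for Il17a and no fall for Il22, not a reinforced fall. Klrg1 (chromosome 6, 122270596 to 122282882) stood at 3062 ± 533 normalized counts in control, 1780 ± 169 with CSF1Ri, 1884 ± 252 with CD40 and 3180 ± 241 with both. Its interaction was 1.53 (adjusted p over the cytotoxic list alone 0.0101). The cytotoxic effector, inhibitory receptor and interferon gamma lists were not among the 10 lists that passed, so a departure from additivity was not shown for them. Of those 10, 7 were positive and 3 negative, and 0 passed with an estimated correlation (adjusted p = 0.93 each). Keratinocyte (10 of 11 positive, adjusted p = 9.23e-05) and ribosomal genes (69 of 76 negative, adjusted p = 8.81e-06) had the smallest p-values, and the type 17 list was positive for 12 of 17 (adjusted p = 0.00501). Of single genes 0 passed over all genes (limma, 655 at an unadjusted p under 0.05), with the smallest p-values for Il17a, the ankyrin gene Ank2 and Anxa8 (adjusted p = 0.565 each). Without CD40 1 the count was 2, Il17a and Il17f, and the type 17 list call ended in 4 of the 10 fits that left out 1 library (adjusted p up to 0.28). The keratinocyte and ribosomal calls held in all 10, and the other 7 ended in 2 to 7 each. The fibroblast and cell cycle calls ended with a Y-linked term (adjusted p of 0.21 and 0.092), and the keratinocyte, NF-kB and fibroblast calls with only the libraries without Y-linked transcripts (0.07, 0.36 and 0.8).

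Averaged over both levels of the antibody, T cell effector lists were higher with the inhibitor at a preset correlation, and no list passed with an estimated correlation (smallest adjusted p = 0.09). Of 100 splits of the libraries, the real one included, 57 gave at least the real 10 lists. Cytotoxic effector (18 of 21 higher, adjusted p = 5.52e-07), inhibitory receptor (17 of 20, adjusted p = 5.06e-06) and interferon gamma response genes (26 of 28, adjusted p = 5.06e-06) rose. With an estimated correlation these had an adjusted p = 0.28, 0.09 and 0.17. T cell identity (19 of 20, adjusted p = 0.000103), type 1 helper (11 of 14, adjusted p = 0.000572) and activation genes (18 of 24, adjusted p = 0.000572) rose, with an adjusted p = 0.28, 0.28 and 0.18 with an estimated correlation. Glycolysis (19 of 21, adjusted p = 0.0348) and cytokine genes (17 of 24, adjusted p = 0.0454) rose, each with an adjusted p = 0.75 with an estimated correlation. Erythroid (5 of 5 lower, adjusted p = 5.53e-09) and keratinocyte genes (9 of 11 lower, adjusted p = 0.0108) fell, with an adjusted p = 0.2 and 0.51 with an estimated correlation. The keratinocyte and T cell identity lists are among those whose interaction passed at the preset correlation, so their averages need not hold at each level of the antibody. Gzmk, Prf1, Entpd1, Pdcd1, Cd38, Il2rb and Bhlhe40 rose over their lists alone, with log2 fold changes of 2.21, 1.19, 1.27, 0.96, 1.62, 0.72 and 0.84. An exact two-sided permutation of the 210 splits of the libraries on the mean level of each list, chosen after seeing the data, gave p = 0.019 for activation, p = 0.0286 for T cell identity and p = 0.0333 for cytotoxic effector genes. It set the 4 libraries with the inhibitor against the 6 without, across the antibody groups, so it is not a test of the averaged effect itself. Over the 38 lists the smallest adjusted p was 0.407. Over all genes 0 passed (limma, 723 at an unadjusted p under 0.05), with the smallest p-values for Anxa8, Cd38 and Entpd1 (adjusted p of 0.655, 0.669 and 0.669). The count was 1, Hbb-bs, without CSF1Ri+CD40 3. The glycolysis call ended in 6 of the 10 fits that left out 1 library (adjusted p up to 0.85), the cytokine call in 5 (0.37) and the keratinocyte call in 4 (0.47), while the other 7 held in all. The glycolysis and cytokine calls ended with a Y-linked term (adjusted p of 0.28 and 0.41), with a Malat1 term (0.33 and 0.45) and with only the libraries without Y-linked transcripts (0.12 and 0.33), where the activation call ended too (0.065).

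Averaged over both levels of the inhibitor, type 17, erythroid and mitochondrially encoded transcripts were lower with the antibody at a preset correlation, and mast cell markers were higher. No list passed with an estimated correlation (smallest adjusted p = 0.21). Of 100 splits of the libraries, the real one included, 31 gave at least the real 13 lists. All 17 type 17 genes were lower on average, 5 of them past the threshold over the list alone. The average joins unlike effects for the cytokines whose interaction passed over the list alone, Il17a, Il22 and Il17f. The log2 fold change of Il17a was -4.10 over control and -0.0176 over CSF1Ri. That of Il22 was -4.09 and 4.04, with an average of -0.0259. The type 17, mitochondrially encoded and ribosomal lists are among those whose interaction passed at the preset correlation, so their averages need not hold at each level of the inhibitor. All 10 mast cell markers were higher, 6 of them past it, and all 5 erythroid genes fell. These 3 lists had an adjusted p = 2.03e-11 each, and an adjusted p = 0.21 each with an estimated correlation. Interferon gamma response (23 of 28 higher, adjusted p = 3.48e-05), inhibitory receptor (14 of 20, adjusted p = 0.0105) and cytotoxic genes (16 of 21, adjusted p = 0.00165) rose, with an adjusted p = 0.21, 0.21 and 0.55 with an estimated correlation. MHC class I (20 of 22, adjusted p = 1.87e-05) and hypoxia genes (13 of 21, adjusted p = 0.0455) rose, each with an adjusted p = 0.25 with an estimated correlation. Glycolysis (18 of 21, adjusted p = 0.000505) and ribosomal genes (60 of 76, adjusted p = 0.00589) rose, with an adjusted p = 0.55 and 0.97 with an estimated correlation. Mitochondrially encoded (7 of 7 lower, adjusted p = 1.87e-05), B cell (13 of 15, adjusted p = 0.0293) and homing receptor genes (19 of 24, adjusted p = 0.0308) fell, with an adjusted p = 0.39, 0.38 and 0.21 with an estimated correlation. Il17a had a log2 fold change of -2.06, Gzmk of 1.94, Lag3 of 1.19 and Arg1, an arginine-degrading enzyme of macrophages, of -4.79, each past the threshold over its list alone.

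An exact two-sided permutation of 252 splits for the antibody, chosen after seeing the data, gave p = 0.00794 for erythroid genes, the smallest it can give, and p = 0.0159 for mast cell and for type 17 genes. It set the 5 libraries with the antibody against the 5 without, across the inhibitor groups, so it is not a test of the averaged effect itself. It gave an exact p = 0.0317 for B cell and p = 0.0476 for hypoxia genes, and over the 38 lists the smallest adjusted p was 0.201. Over all genes 0 passed (limma, 734 at an unadjusted p under 0.05), with the smallest p-values for Hbb-bt, Il17a and the zinc finger gene Zfp763 (adjusted p = 0.242 each). The count was 3, all hemoglobin genes, without CSF1Ri+CD40 3, 1, Il17a, without CD40 1, and 1, Ccl4, without CD40 3. Of the list calls, hypoxia ended in 7 of the 10 fits that left out 1 library (adjusted p up to 0.29), B cell genes in 6 (0.54), homing receptors in 5 (0.17), inhibitory receptors in 4 (0.062), ribosomal genes in 3 (0.76) and glycolysis without CSF1Ri+CD40 1 (0.29). The other 7 held in all 10, with a mean of 0.196 for cytotoxic genes without CD40 1 and 0.49 without CD40 3. The homing receptor call ended with a Y-linked term (adjusted p = 0.086) and with a Malat1 term (0.059), and with only the libraries without Y-linked transcripts the B cell, homing receptor and hypoxia calls ended (0.1, 0.076 and 0.084).

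Some lists passed in none of the 8 comparisons at the preset correlation. Among T cell programs these were naive and memory cells (smallest adjusted p = 0.351), regulatory T cells (0.0972), the type 2 helper program (0.301) and tissue residency (0.118). Among responses they were the type I interferon response (0.0757), cholesterol synthesis (0.118), the unfolded protein response (0.0729) and nuclear-retained noncoding RNA (0.399). Among other cells they were NK cells (0.24), melanocytes and melanoma (0.438), endothelium (0.327), dendritic cells (0.534) and monocytes and neutrophils (0.519).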

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

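The tests of explanations and of other splits given here were chosen after the results were seen, while the interaction was fixed before the data were examined. The interaction, which asks whether the effect of the inhibitor differs with and without the antibody, passed for 10 lists at the preset correlation, each with an adjusted p = 0.93 with an estimated correlation. The adjusted p was 9.23e-05 for keratinocyte markers, 0.0211 for fibroblast markers, 0.00501 for the type 17 program, 0.0211 for cell cycle genes and 0.0211 for the NF-kB response, all positive. It was 0.00929 for immediate early genes and 0.00171 for mitochondrially encoded transcripts, also positive, and 8.81e-06 for ribosomal protein genes, 0.00962 for T cell identity and 0.0461 for oxidative phosphorylation, which were negative. Over the list alone the interaction passed for Il17a (adjusted p = 0.000878 in the type 17 list and 0.00124 among cytokines), Il22 (0.00249 and 0.00351) and Il17f (0.0271). It passed for Klrg1 in the cytotoxic list (adjusted p = 0.0101) and in the regulatory T cell list (0.00957), for Ms4a2 among mast cell markers (0.0344) and for Tnfaip3 in the NF-kB response (0.0224). In the tissue residency list it passed for Ahr, Cd69, Prdm1 and Rgs1 (adjusted p = 0.0491 each).

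Il17a was lower with the CD40 antibody by 4.10 on the log2 scale, and Y-linked transcripts were present in 2 of 3 CD40 libraries and 1 of 3 control libraries. With a term for these transcripts, which rests on the 3 libraries that hold them, the log2 fold change was -3.75 (adjusted p = 0.00471, limma). With only the libraries without them, where CD40 1 is the only CD40 library, it was -3.02. Most of the change remained in both fits, which argues against sex as the whole cause, though few libraries carry this comparison. A smaller share of gamma delta T cells as the whole cause would lower their receptor chains as much, if no other cells transcribe these chains. Trdc, Tcrg-C1 and Tcrg-C2 changed by -0.537 on average (95% interval -1.4 to 0.321), against -5 to -3.2 for Il17a, which argues against it on that condition only. Whether other cells in the libraries transcribe these chains was not measured, and Trdc was itself lower with CD40. A loss of a subset of cells that makes interleukin 17, or less transcript per cell, stays open as a hypothesis, as bulk values do not part them.

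Hemoglobin transcripts were lower with both treatments, with a median log2 fold change of -5.95 over the erythroid list. With a term for Y-linked transcripts the median was -5.77 (adjusted p = 1.62e-12), which argues against sex. Red blood cells bring the hemoglobin genes in a fixed ratio, whether carried through the lysis step or present because treatment changed the blood content, so the ratio does not part these. The largest SD over 9 libraries of the log2 ratio of a hemoglobin gene to Hba-a1 was 0.83, against an SD of 1.72 for log2 Hba-a1 itself. With CSF1Ri+CD40 1, which was left out there because 2 of the genes were at 0 in it, and after adding 1, the values were 1.27 and 2.51. Carry-over and a treatment effect on blood content therefore cannot be told apart, as no value measured here separates them.

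The 69 members of the cytotoxic, inhibitory receptor and interferon gamma lists were higher with both treatments by 0.807 on the log2 scale on average (95% interval 0.319 to 1.3). These lists were taken up after they had passed in this comparison at the preset correlation, and none passed with an estimated one. The interval is therefore no independent test of the rise. With a term for Y-linked transcripts the mean change was 0.688 (0.313 to 1.06), so most of it remained, which argues against sex as its whole cause. With the level of Cd8a and Cd8b1 as a term it was 0.437 (-0.0658 to 0.94), while these genes themselves changed by 1.25 (-0.0182 to 2.52). A larger share of CD8 T cells and higher transcript levels per cell therefore cannot be told apart, since 10 libraries leave the interval wide. The T cell identity list was higher too, at 0.421 and 0.306 in the combination libraries 1 and 3 relative to the control mean. The control libraries ran from -0.0185 to 0.00988. A larger share of all T cells in the libraries was not tested. More transcript per T cell under the combination stays a hypothesis.

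The 3 control and 3 CD40 libraries can be split in 10 ways, too few for a share under 0.05. The real split gave 1 gene and 13 lists, and the highest of the others gave 112 genes and 18 lists. Splits with at least the real count, the real one included, numbered 3 for genes and 4 for lists. The split with 112 genes set control 1, control 3 and CD40 3 against control 2, CD40 1 and CD40 2, so it points to a structure of the samples other than treatment. It follows the level of Malat1, at 45775, 59286 and 95260 normalized counts against 14056, 25034 and 35311, and the sign of the first principal component. The split that follows the Y-linked transcripts gave 3 genes and 9 lists. For the inhibitor averaged over the antibody, 57 of 100 splits, the real one included, gave at least the real 10 lists, the highest being 23. For the antibody averaged over the inhibitor, 31 of 100, again with the real one, gave at least the real 13 lists, the highest being 25. Chance is thus not excluded for the counts of lists of either averaged effect. Both real counts of genes were 0 (limma, 723 and 734 at an unadjusted p under 0.05), which 100 of 100 splits reach by construction, so the splits decide nothing about them; the highest counts of the other splits were 72 for the inhibitor and 1 for the antibody.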

How the results depend on the processing

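The fits with a Y-linked term, with a Malat1 term and with only the 7 libraries without Y-linked transcripts were chosen after seeing the data. Of 4170 values of named genes under the alternatives chosen earlier that use all libraries, 4154 kept their direction and side of the threshold. Of the rest, 10 fell below it and 6 passed it. Without 1 library 3752 of 3786 kept both, and in the 3 added fits 1125 of 1135. Only Anxa8 with CSF1Ri and Il17a with CD40 were past the threshold in the main fit, so the other values had no call to lose. In the same order, 10, 14 and 4 values were losses of these calls, so the shares say little of how well they held. Of 930 list calls without 1 library 757 were kept, 167 were lost and 6 changed the sign of their mean, and in the added fits 235 of 279 were kept. All scalings moved the median of all genes by at most 0.062 on the log2 scale. The 2 alternatives on whole reads were not run, because whole reads could not be recovered. The cause of the differences below was not tested.

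With the estimated correlation the count of lists was 0 in each of the 8 comparisons, and all 93 list calls were lost. In limma without the trend the count of genes was 6 for CSF1Ri, 2 for CD40 (Fam83f and Mtcl1, but not Il17a, adjusted p = 0.132) and 13 for CSF1Ri+CD40 against control, 15 for CSF1Ri+CD40 against CSF1Ri, 9 against CD40, 6 for the interaction, 12 for the averaged CSF1Ri effect and 10 for the averaged CD40 effect. The count for CSF1Ri against control was 0 with a pseudocount of 10 (640 at an unadjusted p under 0.05), with no filter (860), with at least 50 counts (491), with quantile normalization (666), with only the libraries compared (1050) and at the authors' threshold (641). It was also 0 with a Y-linked term (518 at an unadjusted p under 0.05), with a Malat1 term (746) and with only the libraries without Y-linked transcripts (633). Anxa8 is at 0 in both CSF1Ri libraries, so its fitted log2 fold change is set by the pseudocount, at -8.10 with 0.5 and -3.88 with 10, and is not a measured fold. Its adjusted p ran from 0.00366 to 0.795 over 24 alternatives. With only the libraries without Y-linked transcripts, where CD40 1 is the only CD40 library, the call of Il17a ended. The count for CD40 against control was also 0 with no filter (1199 at an unadjusted p under 0.05), with only the libraries compared (722) and with the replicate block (897). For CSF1Ri+CD40 against control it was 1, Hbb-bt, with a pseudocount of 10 and with at least 50 counts.

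Leaving out 1 library gave counts of 0 genes for CSF1Ri, 0 to 3 for CD40 (3 without CD40 1) and 0 to 36 for CSF1Ri+CD40 against control (36 without CSF1Ri+CD40 1). It gave 0 to 6 for CSF1Ri+CD40 against CSF1Ri and 0 to 20 against CD40 (each highest without CSF1Ri+CD40 1), 0 to 2 for the interaction, 0 to 1 for the averaged CSF1Ri effect and 0 to 3 for the averaged CD40 effect. In the same order, genes at an unadjusted p under 0.05 numbered 204 to 882, 676 to 2039, 635 to 1070, 244 to 898, 556 to 1344, 345 to 1297, 358 to 978 and 384 to 1178. The counts of lists were 8 to 15, 9 to 17, 10 to 19, 5 to 13, 5 to 15, 6 to 10, 7 to 14 and 8 to 22 in the same order.

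Some directions turned. The mean log2 fold change over the fits without 1 library ran from -0.128 (without CSF1Ri 1) to 0.431 for inhibitory receptors and from -0.991 to 0.395 (without CSF1Ri 6) for the NF-kB response with CSF1Ri against control. It ran from -0.00151 (without CD40 1) to 0.517 for MHC class II and from -0.00232 (without CD40 2) to 0.341 for oxidative phosphorylation with CD40 against control, and from -0.0826 (without CD40 3) to 0.642 for immediate early genes with CSF1Ri+CD40 against CD40. With CD40 against control, the mean log2 fold change of fibroblast markers ran from -3.01 to 0.422 over the fits without 1 library, against -1.49 with all. Dcn ran from -5.44 to 0.181 and Sparc from -4.23 to 0.0831, each highest without CD40 3. With only the libraries without Y-linked transcripts, the CD40 values are those of CD40 1 alone, against control 2 and control 3. There the log2 fold change averaged 1.33 for fibroblast and 0.269 for keratinocyte markers. It was 0.61 for Col1a1, 1.29 for Dcn, 2.42 for Mmp2, 1.62 for Sparc and 0.88 for Krtdap. In the interaction it was then -0.341 for fibroblast markers and -0.44 for Sparc.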

Other observations

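The genes here were chosen after their values were seen, among the members with the smallest p of their lists, so they do not stand for a group. Values are in the order control, CSF1Ri, CD40 and CSF1Ri+CD40 (mean ± SD, n = 3, 2, 3 and 2). Ahr, a receptor for aryl hydrocarbons that sustains resident lymphocytes, averaged 240 ± 124, 114 ± 87.0, 45.7 ± 20.1 and 206 ± 112 normalized counts. Cd69, a retention and early activation receptor, averaged 6969 ± 783, 5742 ± 302, 4588 ± 1080 and 7806 ± 2290, and Rgs1, a brake on chemokine signaling, 17210 ± 4340, 14290 ± 1710, 10520 ± 2990 and 19680 ± 3790. Prdm1 averaged 504 ± 220, 273 ± 7.07, 241 ± 88.6 and 682 ± 233. The tissue residency list, which holds these 4 genes, passed in none of the 8 comparisons, and its mean level relative to control was 0.202, 0.366 and -0.986 in the CD40 libraries 1, 2 and 3. Lif, a cytokine gene, averaged 80.3 ± 23.2, 31.0 ± 25.5, 8.00 ± 7.21 and 49.0 ± 7.07.

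Il13 averaged 98.7 ± 43.0, 206 ± 111, 324 ± 193 and 171 ± 60.1 normalized counts, and Ccl1, a chemokine that attracts cells with the receptor CCR8, 1407 ± 1020, 3250 ± 260, 7316 ± 6410 and 2467 ± 148. Neither passed over its list with CD40 against control. The type 2 helper list, which holds Il13, passed in none of the 8 comparisons, and its mean level relative to control with CD40 was -0.261. The chemokine gene Ccl4 averaged 1391 ± 417, 1610 ± 41.7, 2492 ± 2010 and 7336 ± 1350, and Ccl5 21070 ± 6730, 26240 ± 286, 19400 ± 12200 and 55100 ± 17300. Library CD40 3, the highest in Malat1, held 188 counts of Ccl4 against 3367 and 3922 in CD40 1 and CD40 2.

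The libraries of the combination differed from each other. Spc25, a kinetochore gene, was at 406 counts in CSF1Ri+CD40 1 and 89 in CSF1Ri+CD40 3, with 408 to 829 in the other groups. Il17re, a subunit of a receptor for interleukin 17, was at 196 and 2. Both genes are among the 35 that were lower than control when CSF1Ri+CD40 1 was left out, and Cd38, at 635 and 1398, was the gene that was higher. CSF1Ri+CD40 3 also had the fewest estimated reads, 10.3 M.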
